A study of Rattus norvegicus with 6 samples.

How the data were processed

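RNA was sequenced from the neuroretina of 6 male GK rat samples, 3 after non-loaded and 3 after spironolactone-loaded microspheres. Per the labels' protocols, retinas were dissected and snap-frozen, total RNA was isolated on columns with DNase treatment, and libraries were made with a stranded mRNA kit. FastQC, Trimmomatic, STAR 2.5.3a, RSEM 1.2.28 and the rn6 genome are named, without roles or parameters, in the submitters' processing notes; the annotation version and the strand setting are not given in the sources used here. If strand was not used in counting, reads of overlapping and antisense genes cannot be told apart. One table per sample was deposited.

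The values used are expected counts per gene, which the authors deposited unnormalised in RSEM gene tables, per the file headers; RSEM shares reads that match several genes between them by likelihood, so paralogous genes such as RT1, globin and ribosomal protein genes are less certain. Between 0.437% and 0.469% of the gene values in a library were fractional. Per the file headers the authors also deposited TPM, used here in an alternative, FPKM, which was not used here in any test, and gene and effective lengths, used in alternatives. No column of another series was present.

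Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the group as argument, which left 13242 of 28358 genes and at least 99.9% of each library's counts. Totals per library lay between 9996198 and 12589466 expected counts. The groups were compared with edgeR 4.0.16 (TMM factors, glmQLFit, glmQLFTest, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Positive values mean higher with spironolactone. The standard error of a log2 fold change is its size over the square root of the F statistic. CPM are normalised with the TMM factors, and a group is given as mean ± SD of 3 libraries. No batch was labelled. The labels' treatment field gave the groups.

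Before the data were examined, 34 gene lists were fixed from textbook knowledge: corticoid signalling, other steroid receptors, Müller water and ion transport, Müller markers, gliosis, microglia, cytokines, complement, MHC and interferon, lymphocytes and neutrophils, endothelium, pericytes, angiogenesis, rods, cones, bipolar, amacrine and horizontal, and ganglion cells, synapses, pigment epithelium, lens, cornea, erythrocytes, oligodendrocytes, matrix, oxidative stress, cell death, immediate early genes, heat shock and unfolded protein response, clock, glucose, cholesterol, mitochondrial genes and cell cycle. Of their 774 different names, 29 were not matched and not analysed here. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside camera with an estimated correlation and fry.

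The genes named were also fixed by a rule beforehand. They are the 12 genes with the smallest p in each direction and the 3 with the largest fold in each, among called genes with a symbol (locus numbers and clone-based names were left out, also where their p was smaller), a mean log2 CPM of at least 0 and groups that do not overlap, 14 corticoid, glial and vascular genes whatever their values, up to 4 members of each list with the smallest p, of which the text gives a part, and 5 sex-linked genes as a check of the labels. Genes named outside the rule are said to be so. Some genes are not reported here, though counts of genes and lists include them.

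The test was checked on simulated counts, drawn for the tested genes from the real means, library sizes and dispersions with 200 genes of mean log2 CPM above 3 changed, in 5 draws of which the first kept 13125 genes. It recovered 45.6% of genes changed 1.25-fold, 88% at 1.5-fold, 99.6% at 2-fold and 100% at 3-fold, and 6.72% of its calls were false. In the same 5 draws a changed list was called 5 times, and 0 of 150 unchanged lists were called. Each gene was drawn independently, so members of these lists did not vary together. The check therefore does not cover correlated lists, such as the rod (estimated correlation 0.439) and mitochondrial (0.739) lists.

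Alternatives were other scalings (RLE, totals, upper quartile), DESeq2 1.42.0, limma-voom with and without sample weights, robust shrinkage, no filter and a filter of 1 CPM in all 6 samples, effective lengths as an offset, log2(TPM + 1) and log2(TPM + 0.1) with limma-trend, thresholds of 0.1 and of 2-fold, and each library left out. A trend against gene length as an offset and the number in the sample title as a covariate were added after seeing the data. Gene order for the neighbourhood test came from the symbols of the GRCr8 assembly, which matched 12620 tested genes (95.3%). That is another build than the one used by the submitters, so no coordinates are given.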

Results

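Gene expression was measured by RNA sequencing in the neuroretina of male Goto-Kakizaki (GK) rats, a non-obese strain that develops type 2 diabetes, at 14 months of age. A volume of 5 µL of microspheres made of the degradable polymer PLGA had been injected into the vitreous once. In 3 samples the microspheres carried 6.2 µg of spironolactone, an antagonist of the mineralocorticoid receptor, and in the other 3 samples they carried no drug. The retinas were taken 2 months after the injection. The non-loaded samples held 9996198, 11572836 and 11966769 expected counts and the spironolactone samples 10575220, 12589466 and 11174928. Of 28358 genes in the tables, 13242 passed the filter on low counts and were tested. The labels do not say whether each sample came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical.

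The Y-linked genes Kdm5d (484 to 694 counts) and Eif2s3y (436 to 566 counts) were counted in all 6 libraries, as the label of male animals requires, while Ddx3y was listed at 0 in all 6. Xist and Uty were not analysed here. Pearson correlations of log2 normalised counts (CPM, counts scaled to a common library total) across genes lay between 0.985 and 0.990 for all pairs of libraries, and counts of each pair differed by more than counting noise (chi-square of 4.03 to 16.2 per gene). Non-loaded replicate 3 was closer to spironolactone replicate 1 (chi-square of 4.76 per gene) than to non-loaded replicates 1 (5.67) and 2 (5.07). The first principal component held 29% of the variance and placed the non-loaded libraries at −17.7, −11 and −5.63 and the spironolactone libraries at 1.61, 10.3 and 22.4. This is also the order of the numbers in the sample titles (2, 3 and 4, then 8, 10 and 11). The component therefore does not separate the groups from that number.

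The single comparison of the design asked how the retinal transcriptome differed after spironolactone-loaded and non-loaded microspheres. The gene with the smallest p among those that rose was Slc7a1, which encodes a transporter of cationic amino acids. It rose from 30.6 ± 7.3 to 114.1 ± 13.6 CPM (SD, n = 3 per group), a log2 fold change of 1.89 ± 0.12 (SE; edgeR quasi-likelihood test, adjusted p = 2.72e-07). Asns, which encodes asparagine synthetase, rose from 79.6 ± 23.6 to 245.3 ± 30.6 CPM (log2 fold change 1.62 ± 0.14, adjusted p = 5.26e-06). Of the 12 genes with the smallest p in this direction, 6 encode cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNAs. Of these, Iars, Tars, Mars, Gars, Nars and Lars rose by log2 fold changes of 0.67 to 1.17, with adjusted p between 5.26e-06 and 1.55e-05. The amino acid transporter genes Slc38a2 (0.83 ± 0.08) and Slc7a5 (0.76 ± 0.08) and the phosphatase gene Dusp8 (0.73 ± 0.07) also rose. The MHC class I gene RT1-A2 rose from 68.5 ± 3.57 to 120.7 ± 11.8 CPM (0.82 ± 0.07, adjusted p = 7.82e-06). The largest folds belonged to the MHC class II gene RT1-Ba, which rose from 0.65 ± 0.24 to 3.38 ± 1.03 CPM (2.36 ± 0.38, adjusted p = 0.00229), to Slc7a1, and to Chac1, which encodes a glutathione-degrading enzyme (25.6 ± 16.2 to 92.2 ± 9.4 CPM, 1.82 ± 0.24, adjusted p = 0.000306). With robust empirical Bayes shrinkage Asns (adjusted p = 0.0634) and Chac1 (adjusted p = 0.175) did not pass. The class I RT1 genes, among them RT1-A2, are close copies of each other, so how their reads were divided is uncertain.

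Among genes that fell, Ccdc125 had the smallest p: it dropped from 66.2 ± 5.51 to 27.3 ± 1.04 CPM (log2 fold change −1.28 ± 0.09, adjusted p = 2.75e-07). Tapbp, which encodes the tapasin that helps load peptides onto MHC class I, fell from 85 ± 4 to 53.4 ± 4.06 CPM (−0.67 ± 0.07, adjusted p = 4.4e-05). Ccdc126 (−0.50 ± 0.06), Ccng1 (−0.46 ± 0.06), the nucleoside transporter gene Slc29a1 (−0.49 ± 0.07), the semaphorin gene Sema7a (−0.51 ± 0.07), Klhl18 (−0.48 ± 0.07), Plpp2 (−0.50 ± 0.08) and Samd7 (−0.40 ± 0.07) fell with adjusted p between 0.000186 and 0.00229. The water channel gene Aqp1 and the rod genes Gnat1 and Rdh12 complete the 12 and are described with their groups. The largest folds among genes that fell were those of RT1-T24-3 (1.61 ± 0.29 to 0.38 ± 0.18 CPM, −2.06 ± 0.47, adjusted p = 0.0262), Vwa7 (2.11 ± 0.33 to 0.71 ± 0.36 CPM, −1.56 ± 0.41, adjusted p = 0.0499) and the glypican gene Gpc3 (2.43 ± 0.90 to 0.84 ± 0.11 CPM, −1.51 ± 0.39, adjusted p = 0.0499). These 3 are expressed near the filter, and their calls depended on which libraries were used. RT1-T24-3 did not pass without any one library (adjusted p between 0.0597, without non-loaded replicate 2, and 0.138, without spironolactone replicate 2). Vwa7 passed only with all 6 or without spironolactone replicate 1 (otherwise 0.0761, without non-loaded replicate 3, to 0.236, without spironolactone replicate 3), and Gpc3 only with all 6 or without non-loaded replicate 2 (otherwise 0.0627, without spironolactone replicate 1, to 0.228, without non-loaded replicate 1).

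In all, 348 genes passed an adjusted p of 0.05, with 247 higher and 101 lower with spironolactone, and 2098 genes had an unadjusted p below 0.05. The changes were small: the median fold of the called genes was 1.30 for those higher and 1.31 for those lower, and 19 higher and 6 lower genes changed at least 2-fold. In 346 of the 348 the libraries of both groups did not overlap. Called genes are selected for a difference that is large against their spread, so this adds no separate support. Over all tested genes the groups did not overlap for 20.9%, against 10% by chance for 3 against 3. Genes vary together between libraries, so this excess is no test of the treatment. Leaving out a library gave 87 higher and 37 lower genes without non-loaded replicate 1, 113 and 44 without non-loaded replicate 2, and 184 and 88 without non-loaded replicate 3. It gave 81 and 30 without spironolactone replicate 2, 105 and 41 without spironolactone replicate 3, and 421 and 200 without spironolactone replicate 1. On log2(TPM + 1) with limma, 82 genes were higher and 18 lower, a share higher of 82% against 71% in the main test. The sample titles carry the numbers 2, 3 and 4 in the non-loaded group and 8, 10 and 11 in the spironolactone group. With that number added to the edgeR model, chosen after seeing the data, 0 genes passed and 562 had an unadjusted p below 0.05 (the only tool run with it). The number follows the group so closely (r = 0.953) that this fit cannot separate them. Each library's deviation from the others of its group was correlated with the group difference over the called genes. This correlation rose in number order in both groups: −0.59, −0.21 and 0.6 (non-loaded) and −0.47, 0 and 0.46 (spironolactone). Over all tested genes it lay between −0.14 and 0.15. The deviations within a group balance each other, so only their order is informative.

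**Figure D1:**
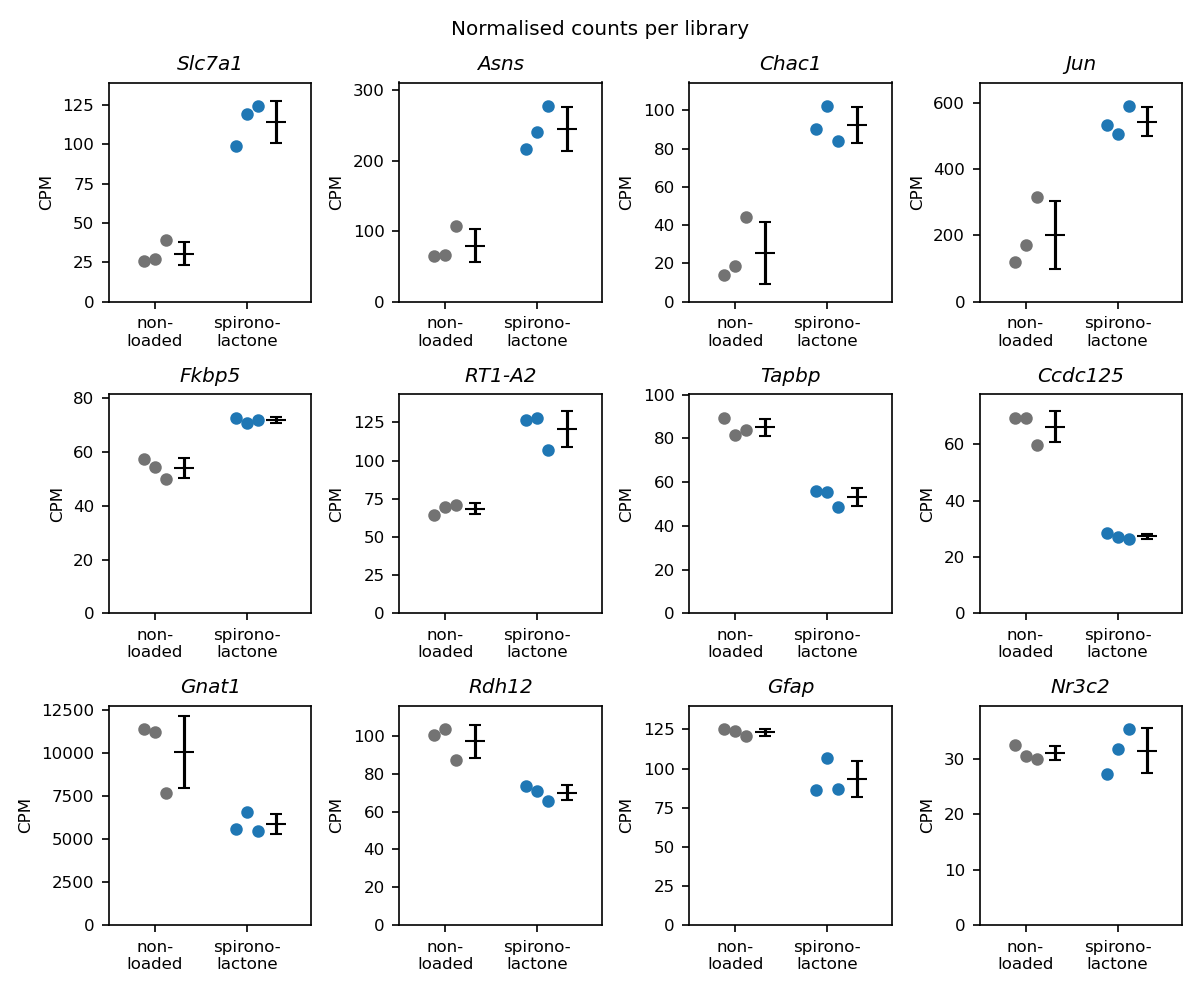
Normalised counts (CPM, linear axes from 0) of 12 genes in the 3 non-loaded (grey) and 3 spironolactone (blue) libraries, each point a library, with the group mean and SD beside them in black. The groups did not overlap for Slc7a1 (25.6 to 39 against 98.6 to 124.3 CPM), whereas they did for the mineralocorticoid receptor gene Nr3c2 (31 ± 1.3 against 31.5 ± 4.05 CPM).

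Neither corticoid receptor gene passed the test. Nr3c2, the mineralocorticoid receptor and target of the drug, measured 31 ± 1.3 and 31.5 ± 4.05 CPM (log2 fold change 0.02 ± 0.10, adjusted p = 0.947), and the glucocorticoid receptor gene Nr3c1 145.6 ± 2.27 and 144 ± 5.1 CPM (−0.02 ± 0.06, adjusted p = 0.934). The same held for the corticoid-induced kinase gene Sgk1 (−0.02 ± 0.06, adjusted p = 0.933), Tsc22d3 (−0.04 ± 0.08, adjusted p = 0.848), Per1 (0.13 ± 0.06, adjusted p = 0.283) and the sodium channel gene Scnn1a (−0.10 ± 0.37, adjusted p = 0.934). Fkbp5, a co-chaperone of steroid receptors that corticoids induce, rose from 54 ± 3.72 to 71.8 ± 1.06 CPM (0.41 ± 0.07, adjusted p = 0.00362) and the transcription factor gene Klf9 from 146.3 ± 5 to 186 ± 8.05 CPM (0.35 ± 0.06, adjusted p = 0.00315), whereas Arl4d fell (−0.36 ± 0.08, adjusted p = 0.019). Arl4d did not pass without non-loaded replicate 1 (adjusted p = 0.112), non-loaded replicate 2 (0.0705) or spironolactone replicate 3 (0.0674). Of the 19 tested members of the mineralocorticoid and glucocorticoid signalling list, 2 rose and 1 fell, the same counts adjusted over the list alone, and the list did not pass the set test (camera, adjusted p = 0.281). Hsd11b1 (at most 12 counts) and Hsd11b2 (at most 7 counts), whose enzymes interconvert active and inactive glucocorticoids, were below the filter, so a change in them was not detectable at this depth. The list of other steroid receptors and xenobiotic response had 0 of 11 members called (0 adjusted over the list alone). Its median log2 fold change was 0.01 and its mean −0.07. Its set test pointed down (adjusted p = 0.793).

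Rod photoreceptor genes were in part lower. Of 23 tested rod markers 10 were lower and 1 was higher (13 and 1 adjusted over the list alone), with a median log2 fold change of −0.19 (camera, adjusted p = 3.34e-14). With an estimated correlation between the genes the list did not pass (adjusted p = 0.424). Gnat1, the rod transducin alpha subunit, fell from 10070 ± 2090 to 5864 ± 588 CPM (−0.78 ± 0.11, adjusted p = 0.000705), Reep6 fell by 0.63 ± 0.11 on the log2 scale, Rom1, an outer segment disc protein, by 0.54 ± 0.09, and Rdh12, a retinol dehydrogenase, by 0.47 ± 0.07. The member that rose, named after its value was seen, was Crx, a transcription factor of photoreceptors (0.24 ± 0.06, adjusted p = 0.0286). Crx did not pass without non-loaded replicate 1 (0.158), non-loaded replicate 2 (0.133), spironolactone replicate 2 (0.145) or spironolactone replicate 3 (0.0643). Gnat1 (0.162), Rom1 (0.0707) and Reep6 (0.218) did not pass with robust empirical Bayes shrinkage. Markers of the pigment epithelium and choroid, which adjoin the rods and can adhere to a dissected retina, were lower in the same comparison: 0 of 16 were called (0 adjusted over the list alone), the median was −0.12 and the set test gave an adjusted p of 0.0294 (0.627 with an estimated correlation). That call was lost without spironolactone replicate 3 (0.4), non-loaded replicate 1 (0.0669) or non-loaded replicate 3 (0.0603). Rpe65 measured 15.3 ± 3.55 and 10.1 ± 4.43 CPM (adjusted p = 0.232, and 0.0255 without spironolactone replicate 1).

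**Figure D2:**
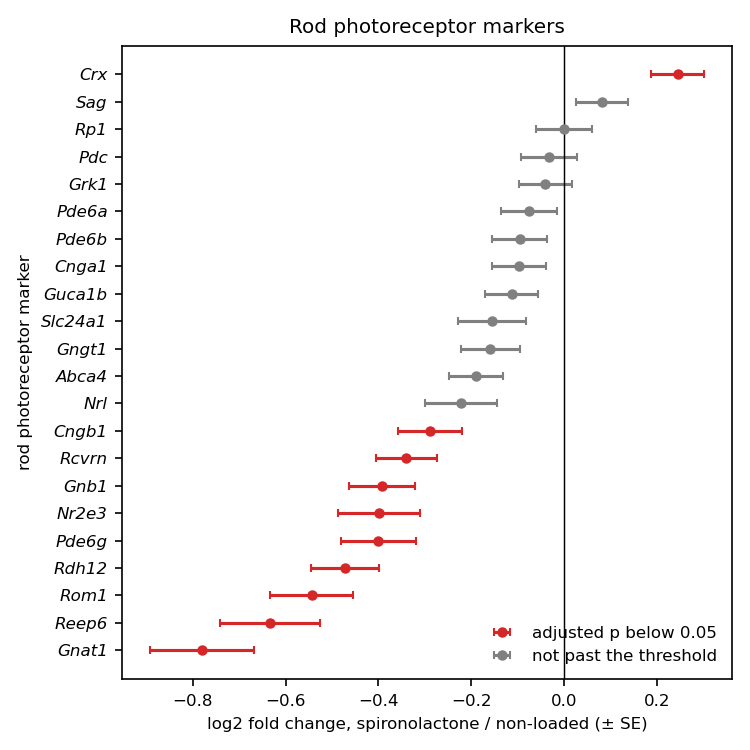
Log2 fold change (spironolactone over non-loaded, horizontal axis) with its SE for 22 of the 23 tested rod markers (vertical axis), red where the adjusted p was below 0.05 and grey elsewhere. The points run from −0.78 for Gnat1 to 0.24 for Crx, with 9 red points below 0 and 1 above.

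For other retinal neurons no list passed. Cone markers had 0 of 15 members called (1 lower adjusted over the list alone; median −0.12, adjusted p = 0.0736, and 0.0421 without non-loaded replicate 2 and 0.0451 without spironolactone replicate 2). The counts were 0 of 16 for bipolar cell markers (median −0.03, adjusted p = 0.751), 0 of 20 for amacrine and horizontal cell markers (1 higher adjusted over the list alone, the glycine transporter gene Slc6a9 at 0.19 ± 0.05; median −0.04, adjusted p = 0.336), 0 of 19 for ganglion cell markers (median −0.01, adjusted p = 0.914, with fry pointing up and camera down) and 0 of 31 for synaptic transmission genes (median −0.02, adjusted p = 0.333). Adjusted over the list alone, the bipolar, ganglion cell and synaptic lists also had 0 calls.

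Some genes on the lists for Müller glia, the glial cells that regulate water and potassium in the retina, were lower. In bulk tissue, the cells in which these genes, Aqp1 among them, changed were not determined. Of 18 members of the Müller water and ion transport list, 0 rose and 2 fell (also 0 and 2 adjusted over the list alone), with a median of −0.11 (camera, adjusted p = 0.00381, and adjusted p = 0.424 with an estimated correlation). Aqp1 fell from 89.8 ± 8.63 to 60.8 ± 7.1 CPM (−0.56 ± 0.09, adjusted p = 0.00135), although it did not pass on log2(TPM + 1) (adjusted p = 0.0675). The main water channel gene of these cells, Aqp4, measured 209.1 ± 6.5 and 199.2 ± 8.25 CPM (−0.07 ± 0.06, adjusted p = 0.608), and the potassium channel gene Kcnj10 31.5 ± 2.11 and 26.9 ± 4.81 CPM (−0.22 ± 0.12, adjusted p = 0.363). Of 20 general Müller markers 2 fell and 0 rose (the same adjusted over the list alone; median −0.04, adjusted p = 0.0294, and adjusted p = 0.44 with an estimated correlation), a set call that was lost without non-loaded replicate 3 (0.183) or spironolactone replicate 1 (0.0926). They were Crym (−0.32 ± 0.06, adjusted p = 0.0104, and 0.0506 without spironolactone replicate 3) and Dbi (−0.37 ± 0.09, adjusted p = 0.0464), which passed only with all 6 libraries or without non-loaded replicate 3 or spironolactone replicate 1 (otherwise between 0.146, without non-loaded replicate 2, and 0.215, without spironolactone replicate 2).

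Among genes of reactive gliosis, Gfap, the intermediate filament gene of activated glia, fell from 123.2 ± 2.3 to 93.4 ± 11.3 CPM (−0.40 ± 0.07, adjusted p = 0.00655, and 0.0913 on log2(TPM + 1)). Cebpb, a transcription factor gene, rose from 10.6 ± 2.32 to 23.6 ± 2.17 CPM (1.15 ± 0.14, adjusted p = 0.000186). Lcn2 measured 11.2 ± 1.52 and 16.4 ± 9.23 CPM (0.54 ± 0.27, adjusted p = 0.344, and 0.0291 without spironolactone replicate 1). Gfap and Cebpb were the only calls among the 21 members, also when adjusted over the list alone, and the list did not pass (median −0.05, adjusted p = 0.706).

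In the MHC and interferon list 3 of 33 members rose (RT1-A2, RT1-Ba and Cd74) and 2 fell (Tapbp and Ifi27). Adjusted over the list alone the counts were 4 and 2, and the list did not pass (median 0.07, adjusted p = 0.0958, and 0.0111 without non-loaded replicate 3). Cd74, the invariant chain of MHC class II, rose from 5.76 ± 3.38 to 12 ± 1.78 CPM (1.04 ± 0.27, adjusted p = 0.0499) and did not pass without non-loaded replicate 1 (0.225), non-loaded replicate 2 (0.172), spironolactone replicate 2 (0.255) or spironolactone replicate 3 (0.124). Ifi27 (−0.50 ± 0.12, adjusted p = 0.0448) was lost without non-loaded replicate 1 (0.16), non-loaded replicate 3 (0.161), spironolactone replicate 2 (0.102) or spironolactone replicate 3 (0.193). Cd74 was the only one of 24 microglia and macrophage markers called (1 adjusted over the list alone; median 0.05, adjusted p = 0.383, and 0.0104 without non-loaded replicate 3). The cytokine, chemokine and NF-kB list had 0 of 17 members called (median 0.09, adjusted p = 0.208) and complement 0 of 16 (median 0.04, adjusted p = 0.706), or 0 and 2, 1 in each direction, adjusted over the list alone. Of the lymphocyte and neutrophil markers only Cd4 was tested (9.47 and 8.62 CPM, −0.15 ± 0.21, adjusted p = 0.799).

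Angiogenic and hypoxia genes held 3 calls among 23 members, all higher (4 adjusted over the list alone). Vegfa, the vascular growth factor gene, rose from 171.7 ± 8.03 to 233.4 ± 15.8 CPM (0.44 ± 0.06, adjusted p = 0.000691). Vldlr, a lipoprotein receptor gene, rose from 117.2 ± 6.59 to 166.9 ± 1.62 CPM (0.51 ± 0.06, adjusted p = 9.67e-05). Epas1, a hypoxia-inducible transcription factor gene, rose by 0.24 ± 0.06 (adjusted p = 0.0351), but not without non-loaded replicate 1 (0.137), non-loaded replicate 2 (0.164), spironolactone replicate 2 (0.106) or spironolactone replicate 3 (0.15). The median of the list was −0.01, its mean 0.05 and its set test pointed up without passing (adjusted p = 0.18). Of 24 endothelial and barrier markers 1 was called (1 adjusted over the list alone; median −0.03, adjusted p = 0.895, with fry pointing up and camera down). It was the clotting factor gene Vwf (0.55 ± 0.14, adjusted p = 0.0404), which passed only with all 6 libraries or without spironolactone replicate 2 (otherwise between 0.0679, without non-loaded replicate 3, and 0.163, without non-loaded replicate 2). The tight junction gene Cldn5 measured 36.6 and 30.4 CPM (−0.27 ± 0.13, adjusted p = 0.346, and 0.043 without spironolactone replicate 1). Pericyte and smooth muscle markers had 0 of 13 called (0 adjusted over the list alone; median 0.07, mean −0.03, set test down, adjusted p = 0.729), and matrix and TGF-beta genes 0 of 32 (0 adjusted over the list alone; median −0.01, mean 0.10, set test up, adjusted p = 0.983).

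The heat shock and unfolded protein response list rose by the set test (camera, adjusted p = 0.0036, and adjusted p = 0.44 with an estimated correlation), with 6 of 20 members higher and 0 lower (7 and 2 adjusted over the list alone). Its median was 0.02 and its mean 0.23. The members that rose were not heat shock chaperones: Asns and Chac1, given above, Sesn2 (92 ± 41.4 to 247.5 ± 23.3 CPM, 1.42 ± 0.19, adjusted p = 0.000305), a stress-induced regulator of mTOR signalling, and Ddit3 (0.40 ± 0.08, adjusted p = 0.0109), a transcription factor gene of the integrated stress response. Herpud1 (0.48 ± 0.10, adjusted p = 0.0145) and the pseudokinase gene Trib3 (0.53 ± 0.13, adjusted p = 0.0455) also rose, and the chaperone genes Hspa5 (−0.11 ± 0.06, adjusted p = 0.45) and Dnajb1 (−0.17 ± 0.06, adjusted p = 0.15) did not pass. These last 4 were named after their values were seen. Ddit3 did not pass without non-loaded replicate 1 (0.0781), non-loaded replicate 2 (0.062) or spironolactone replicate 2 (0.112), Herpud1 without the same libraries (0.0647, 0.0559 and 0.143), and Trib3 without them (0.217, 0.175 and 0.219) or spironolactone replicate 3 (0.104).

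Cell death and axon injury genes also rose as a list (adjusted p = 0.0131, and adjusted p = 0.424 with an estimated correlation), with 4 of 21 higher and 1 lower (the same adjusted over the list alone), a set call lost without spironolactone replicate 1 (0.0728). Its median was 0.06 and its mean 0.18. Those higher included the transcription factor genes Atf3 (57.3 ± 22.7 to 133.8 ± 12.6 CPM, 1.21 ± 0.16, adjusted p = 0.000384), Jun (202.6 ± 103 to 543.1 ± 43.9 CPM, 1.42 ± 0.21, adjusted p = 0.000945) and Ddit3. Gadd45b fell (−0.38 ± 0.09, adjusted p = 0.0262), though not without non-loaded replicate 1 (0.137), non-loaded replicate 2 (0.0838), spironolactone replicate 2 (0.0817) or spironolactone replicate 3 (0.124). With robust empirical Bayes shrinkage Atf3 (0.176), Jun (0.221) and Sesn2 (0.174) did not pass. Among 22 immediate early genes 4 rose and 0 fell (4 and 1 adjusted over the list alone): Atf3, Jun, the neuronal activity gene Npas4 (5.16 ± 0.92 to 13.4 ± 4.05 CPM, 1.38 ± 0.22, adjusted p = 0.00163) and Jund (0.36 ± 0.08, adjusted p = 0.0213), the last not without non-loaded replicate 1 (0.132), non-loaded replicate 2 (0.121) or spironolactone replicate 2 (0.155). The median of this list was −0.01, its mean 0.07 and its set test pointed up without passing (adjusted p = 0.438, and 0.00291 without non-loaded replicate 3). In the oxidative stress list only the transcription factor gene Nfe2l2 was called among 25 members (1 adjusted over the list alone), at 37.2 ± 7.97 and 56.8 ± 4.32 CPM (0.60 ± 0.12, adjusted p = 0.00785). It did not pass without non-loaded replicate 1 (0.0613), non-loaded replicate 2 (0.0507) or spironolactone replicate 2 (0.0786), and the list had a median of −0.01, a mean of 0.02 and a set test pointing down (adjusted p = 0.729).

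Of 20 circadian clock genes 2 rose and 0 fell (2 and 1 adjusted over the list alone): Ciart, a repressor of the clock, from 16.1 ± 1.84 to 30.2 ± 4.51 CPM (0.91 ± 0.12, adjusted p = 0.000407) and the core clock gene Arntl (0.26 ± 0.06, adjusted p = 0.0152), the latter not without non-loaded replicate 1 (0.0877), non-loaded replicate 2 (0.0803) or spironolactone replicate 2 (0.0856). Per2 measured 34 ± 0.83 and 27.1 ± 0.85 CPM (−0.33 ± 0.09, adjusted p = 0.0525). The clock list did not pass (median 0.06, adjusted p = 0.0736, and 0.0427 without non-loaded replicate 1).

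Glucose and insulin metabolism fell as a list (adjusted p = 0.0131, and adjusted p = 0.44 with an estimated correlation), with 3 of 30 lower and 0 higher (5 and 0 adjusted over the list alone), a set call lost without non-loaded replicate 1 (0.0669) or spironolactone replicate 2 (0.0569). Its median was −0.03 and its mean −0.06. The 3 encode glycolytic enzymes: Pkm (1974 ± 155 to 1512 ± 62.3 CPM, −0.39 ± 0.07, adjusted p = 0.00307), Gapdh (2119 ± 115 to 1615 ± 132 CPM, −0.39 ± 0.07, adjusted p = 0.00324, and 0.0584 without spironolactone replicate 2) and Ldha (−0.37 ± 0.08, adjusted p = 0.0182), which was lost without non-loaded replicate 1 (0.113), non-loaded replicate 2 (0.069), spironolactone replicate 2 (0.159) or spironolactone replicate 3 (0.0952). Gapdh has many processed pseudogenes, so its count is uncertain. The cholesterol and lipid list had 0 of 33 members called (0 adjusted over the list alone) but was lower by the set test (median −0.06, adjusted p = 0.0294, and adjusted p = 0.424 with an estimated correlation), not without non-loaded replicate 1 (0.0749) or spironolactone replicate 1 (0.101). Mitochondrially encoded genes were higher by the set test with 0 of 12 called (0 adjusted over the list alone; median 0.13, adjusted p = 0.0395, and adjusted p = 0.717 with an estimated correlation). That call was lost without non-loaded replicate 1 (0.115), non-loaded replicate 3 (0.278), spironolactone replicate 2 (0.243) or spironolactone replicate 3 (0.515). Mitochondrial mRNA took 4.98 ± 0.32% of the counts in the non-loaded group and 5.42 ± 0.68% in the spironolactone group. The cell cycle list had 0 of 16 members called (0 adjusted over the list alone; median −0.07, adjusted p = 0.465).

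Lists of genes of other tissues, apart from the pigment epithelium list given above, did not pass the set test where they had enough members for one. The lens list had 0 of 5 tested members called (median −0.17, adjusted p = 0.465), the cornea, conjunctiva and ciliary epithelium list 0 of 11 (median 0.03, adjusted p = 0.465) and the oligodendrocyte list 0 of 9 (median −0.20, adjusted p = 0.163), all with 0 adjusted over the list alone. The corneal keratin gene Krt12 stood at 25.1 CPM in spironolactone replicate 1 and between 0.2 and 1.89 CPM in the other libraries (adjusted p = 0.103, and 0.0415 without spironolactone replicate 3). Of 2 tested erythrocyte genes the haemoglobin gene Hba-a2 was higher, at 61.2 ± 5.85 and 91.5 ± 23.9 CPM (0.58 ± 0.14, adjusted p = 0.0304, 1 adjusted over the list alone), and passed only with all 6 libraries or without spironolactone replicate 3 (otherwise between 0.0541, without spironolactone replicate 1, and 0.224, without spironolactone replicate 2). Its reads can be shared with other alpha-globin genes. Hbb measured 33.9 and 38.3 CPM (adjusted p = 0.724).

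Of 32 lists tested, 3 were higher and 6 lower at an adjusted p of 0.05 by camera with a preset correlation of 0.01. With an estimated correlation 0 lists passed and 3 had an unadjusted p below 0.05. By fry 0 lists passed, while 17 passed its mixed test, which asks whether members change in either direction.

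Several of the calls above ended under another setting of the test. On log2(TPM + 1) the calls of Aqp1, Plpp2, Rom1, Reep6, Crx, Gfap, Crym, Dbi, Arl4d and Nfe2l2 were lost. So were those of Pkm, Gapdh, Ldha, Ddit3, Herpud1, Trib3, Gadd45b, Jund and Arntl. Those of Cd74, Ifi27, Epas1, Vwf, Hba-a2, Vwa7 and Gpc3 were lost too, with adjusted p over all these genes from 0.0553 for Pkm to 0.265 for Vwf. RT1-T24-3 was lost on log2(TPM + 0.1) (0.0718). With robust shrinkage Cd74 (0.232), Vwf (0.125), Hba-a2 (0.36), Herpud1 (0.204) and Trib3 (0.278) were lost as well. Calls near the threshold also moved with scaling or tool. Cd74 (0.0525), Dbi (0.0532), Gpc3 (0.052), Vwa7 (0.0525), Trib3 (0.0531) and Ifi27 (0.0514) did not pass with library totals. With upper-quartile factors Cd74 (0.0567), Gpc3 (0.0521), Vwa7 (0.0521) and Trib3 (0.0521) did not pass, nor Vwa7 (0.0506) with RLE factors. With effective lengths RT1-T24-3 (0.0539), Vwa7 (0.058), Gpc3 (0.0577), Dbi (0.0539), Cd74 (0.0637) and Trib3 (0.0568) did not pass, and Dbi (0.0778) did not with the length trend removed. Trib3 (0.206), Herpud1 (0.0807) and Hba-a2 (0.183) did not pass with DESeq2. With voom Gpc3 (0.0853), Ifi27 (0.0512), Vwf (0.0635) and Hba-a2 (0.0512) did not pass, and with its sample weights Gpc3 (0.0941), Ifi27 (0.0637) and Vwf (0.0748) did not. In the other direction Slc6a9 passed with DESeq2 (0.00522), voom (0.0364), voom sample weights (0.0269), robust shrinkage (0.0382), no filter (0.0482) and the length trend removed (0.039). Per2 passed with upper-quartile factors (0.0499), voom sample weights (0.0421), robust shrinkage (0.0468), no filter (0.0461) and the length trend removed (0.0271). Krt12 (7.55e-06) and Rpe65 (0.0332) passed with no filter.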

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

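The length trend and title number fits were chosen after seeing the data. No paired analysis was possible because the groups share no replicate number in the sample titles. The counts of 247 higher and 101 lower genes stayed within 1.5 times under RLE, totals and upper-quartile scaling, DESeq2, both voom fits, robust shrinkage, the strict filter, effective lengths and the length trend (215 to 307 higher, 84 to 123 lower; 292 to 340 of the 348 genes were shared). They moved to 439 and 163 with no filter, which tests more genes, to 82 and 18 on log2(TPM + 1), to 79 and 16 on log2(TPM + 0.1) (share higher 83.2%), to 416 and 177 at an adjusted p of 0.1 and to 19 and 6 with a 2-fold minimum. The cause of the lower counts on TPM was not tested. Leaving out 1 library gave 81 to 421 higher and 30 to 200 lower genes: the lowest without spironolactone replicate 2, the highest without spironolactone replicate 1, and 87 and 37, 113 and 44, and 105 and 41 without non-loaded replicates 1 and 2 and spironolactone replicate 3. Without non-loaded replicate 3 the counts were 184 and 88, within 1.5 times of the main ones. With the title number as a covariate the counts were 0 and 0 (562 genes at an unadjusted p below 0.05). It shares most of its variance with the group (variance inflation of 11), which by construction widens the errors. Of the genes named, called ones changed sign under this covariate alone, none past the threshold, to log2 fold changes of Klhl18 0.078, Plpp2 0.144, Aqp1 0.177, Vwa7 0.64, Arl4d 0.202, Rom1 0.298, Dbi 0.306, Cd74 −0.302, Herpud1 −0.199, Trib3 −0.005, Npas4 −0.224, Nfe2l2 −0.249, Pkm 0.001, Gapdh 0.116, Ldha 0.377, Slc1a4 −0.313, Mthfd2 −0.062, Rps14 0.253, Rpl9 0.361, Ndufa4 0.055, Ndufb2 0.06, Cep290 −0.111, Ift74 −0.059, Cep126 −0.128, Pgam1 0.271.

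For lists, the 3 higher and 6 lower became 0 and 0 with an estimated correlation, which uses a correlation measured for each list, and 0 and 0 with fry, which asks another question. The measured correlation was 0 for Müller water and ion transport, −0.011 for cell death and 0.004 for cholesterol, not above the preset 0.01. Their unadjusted camera p still rose, from 0.000357 to 0.0183, 0.00204 to 0.0278 and 0.00736 to 0.0446. Correlation between members therefore does not account for the loss of those calls. Leaving out 1 library gave 2 to 5 higher and 3 to 7 lower lists, with 5 higher without non-loaded replicate 3 and 3 lower without non-loaded replicate 1. Over all alternatives, 1612 of 1944 values of named genes stayed on their side of the threshold, 18 of them uncalled and with the sign changed, while 290 lost and 17 gained a call and 25 called ones changed sign. For lists 313 of 351 stayed, 21 of them with the sign changed, 32 lost and 6 gained a call, and 0 reversed. The causes were not tested otherwise. At the depth, spread and number of these libraries, which were not varied separately, the smallest simulated change was recovered in 45.6% of cases.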

Other observations

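The gene families, the title number, rod share, MHC neighbourhood, neighbour pair and microglia tests, and the split of the samples by genes, were chosen after results were seen, and so was the use of a length trend, whose tests on the patterns were written down before their results, as were the splits by lists. Families were counted by symbol. The synthetase, transporter and one-carbon families were chosen because changed members had been seen, so their p-values describe that choice and are no independent test. Of 20 cytosolic aminoacyl-tRNA synthetases 11 rose and 0 fell, with a median of 1.46-fold (camera, adjusted p = 0.03 over 8 families with an estimated correlation). In contrast, 0 of 16 mitochondrial synthetases were called (median 1.02-fold, adjusted p = 0.656). The difference between these families was not tested. Of 23 amino acid transporters 5 rose, Slc7a1, Slc38a2, Slc7a5, Slc3a2 (0.60 ± 0.07, adjusted p = 0.000107) and Slc1a4 (0.94 ± 0.16, adjusted p = 0.00339), with a family median of −0.03 (adjusted p = 0.0338). In serine, glycine and one-carbon synthesis 2 of 7 rose, Shmt2 (0.48 ± 0.08, adjusted p = 0.0035) and Mthfd2 (0.71 ± 0.16, adjusted p = 0.0243), with a family adjusted p of 0.0861. Mthfd2 was lost without non-loaded replicate 1 (0.0989), non-loaded replicate 2 (0.11), spironolactone replicate 2 (0.138) or spironolactone replicate 3 (0.0649), with DESeq2 (0.223), with robust shrinkage (0.37) and on log2(TPM + 1) (0.141). Slc1a4 was lost with robust shrinkage (0.252) and on log2(TPM + 1) (0.082). Atf4, whose protein activates many of these genes and is controlled mainly in translation, measured 798.6 ± 20.1 and 886.5 ± 37.6 CPM (0.15 ± 0.06, adjusted p = 0.187).

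Abundant housekeeping families leaned lower without passing an estimated correlation, with members named after their values were seen. Of 15 glycolytic enzymes 4 were lower (median 0.888-fold, adjusted p = 0.13), Pkm, Gapdh and Ldha, given above, and Pgam1 (−0.28 ± 0.07, adjusted p = 0.0417). Of 72 nuclear-encoded respiratory chain subunits 5 were lower (median 0.904-fold, adjusted p = 0.13), Atp5l (−0.35 ± 0.07), Ndufa4 (−0.42 ± 0.09), Cox8a (−0.28 ± 0.06), Cox6a1 (−0.24 ± 0.06) and Ndufb2 (−0.39 ± 0.10), with adjusted p from 0.00905 to 0.0444. Of 70 cytosolic ribosomal proteins 2 were lower (median 0.938-fold, adjusted p = 0.259), Rps14 (−0.41 ± 0.09, adjusted p = 0.021) and Rpl9 (−0.40 ± 0.10, adjusted p = 0.0351), whose reads can be shared with pseudogenes. Of 50 centrosomal and intraflagellar transport genes 4 were higher (median 1.07-fold, adjusted p = 0.13), Cep290 (0.54 ± 0.08), Ift74 (0.61 ± 0.10), Cep126 (0.52 ± 0.10) and Ift81 (0.33 ± 0.07), with adjusted p from 0.000842 to 0.0119. Atp5l, Cep290 and Ift74 passed without each library in turn. Without non-loaded replicate 1 the calls of Pgam1 (0.187), Ndufa4 (0.0801), Cox8a (0.101), Cox6a1 (0.111), Ndufb2 (0.162), Rps14 (0.0871), Rpl9 (0.137), Cep126 (0.0661) and Ift81 (0.062) were lost. Without non-loaded replicate 2 those of Pgam1 (0.107), Ndufa4 (0.0704), Cox6a1 (0.119), Ndufb2 (0.16) and Rpl9 (0.0513) were lost. Without non-loaded replicate 3 those of Pgam1 (0.0603), Cox6a1 (0.0591), Rps14 (0.069), Rpl9 (0.0987) and Ift81 (0.0607) were lost. Without spironolactone replicate 2 those of Pgam1 (0.207), Ndufa4 (0.0694), Cox8a (0.145), Cox6a1 (0.0754), Ndufb2 (0.199), Rps14 (0.155), Rpl9 (0.214) and Ift81 (0.0905) were lost. Without spironolactone replicate 3 those of Pgam1 (0.187), Ndufa4 (0.0635), Cox6a1 (0.108), Ndufb2 (0.17), Rps14 (0.0952), Rpl9 (0.158) and Ift81 (0.0635) were lost. With the length trend removed Cox8a (0.0801), Cox6a1 (0.0845) and Ndufb2 (0.0908) did not pass. On log2(TPM + 1) Pgam1, Ndufa4, Cox8a, Cox6a1, Ndufb2, Rps14, Rpl9 and Cep126 did not pass, with adjusted p from 0.0632 for Ndufb2 to 0.223 for Rpl9. Rpl9 was also lost with robust shrinkage (0.16) and effective lengths (0.0544). No family median changed sign under RLE, totals or upper-quartile scaling. Genes called higher were longer (median 2878 bases) than genes called lower (1742 bases), with 2323 bases over all tested genes.

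The first pattern is the rise of 24 called genes of amino acid supply and stress (the synthetases, transporters, one-carbon genes and called members of the heat shock and unfolded protein response list). Their mean log2 CPM was 6.47, 6.61 and 7.01 in the non-loaded libraries with title numbers 2, 3 and 4, and 7.56, 7.66 and 7.70 in the spironolactone libraries with 8, 10 and 11. A gene length trend as the whole cause is argued against by its size. Over all tested genes in 5 length classes, the median log2 fold change was −0.03 in the shortest and 0.022 in the longest. The calls were more unequal, with 27 higher and 33 lower in the shortest class and 72 and 9 in the longest. Removing the small trend over all genes could change little: a share of 1 (24 of 24) stayed past the threshold, with a median of 0.80 against 0.81. A gradient along the title numbers, whatever they record, stays open: the slope within groups predicts 0.799 of the gap (1.88 from the non-loaded and 0.335 from the spironolactone libraries alone), both groups lie in number order, which had been seen before the number was tested, and with the number in the model the median was 0.22, with 19 of 24 genes positive. Spironolactone, such a gradient and handling that differed with it cannot be told apart, because number and group almost coincide.

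The second pattern is the fall of 10 called rod genes. A lower share of rods would lower rod markers alike if all were expressed in rods alone. Their log2 changes had an SD 3.72 times their median SE (3.35 times without Crx, which is not specific to rods). The prediction written for a lower share of rods also had markers of other neurons rise. The 70 cone, bipolar, amacrine and horizontal, and ganglion cell markers had a median log2 change of −0.037, with 26 positive. That rise was thus not seen, but no spread was computed for this median, so it does not decide. How specific the rod markers other than Crx are was not tested, and shared markers would fall unequally under a loss of rods too. Whether a loss of rods was the whole cause, or acted beside another change, therefore stays open. A gene length trend as the whole cause is argued against by the same small medians of the length classes. With that trend removed a share of 1 (10 of 10) stayed past the threshold. The title number slope predicts 1.06 of the gap, with neither group in exact number order because libraries of nearly equal level (10.52 and 10.55, 10.03 and 10.05 mean log2 CPM) exchange places, and with the number in the model the median was 0.03, so it cannot be told apart from spironolactone. A change of rod gene expression with treatment remains a hypothesis, untested beyond the group labels.

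The third pattern is in the MHC region, which was looked at because called genes had been seen in it. Between the outermost RT1 genes and 10 genes beyond them, 11 of 110 tested genes were called, 5 higher and 6 lower (10% against 2.63% elsewhere, Fisher's exact p = 0.000182), and without the RT1 genes 6 of 92 (Fisher's exact p = 0.0358), values that restate why the region was chosen, over genes that are not independent and class I RT1 copies that can share reads. Over all chromosomes called genes were not shown to lie closer together than chance (94 pairs within 10 neighbours, random median 90, one-sided permutation p = 0.364). That test covers all genes at once and can miss a difference confined to 1 region. An inherited difference between the animals of the groups and a drug effect cannot be told apart here, with no genotype to decide. The other 23 microglia and macrophage markers had a median of 0.039 (0.16 at 2 standard errors above it), below 0.52, which is Cd74's log2 change divided by 2. Without each library in turn the median also stayed below that measure. It was highest without non-loaded replicate 3, where the list passed as higher (camera, adjusted p = 0.0104), at 0.254 (0.38 at 2 standard errors above it) against 0.82. These standard errors were taken over the markers and leave out the spread between libraries. Within these libraries only, the markers argue against a general rise of microglia and macrophages by enough to bring the change of Cd74. Of these markers 3 had an unadjusted p below 0.05, all 3 higher, and a small number of cells rich in class II stays open for RT1-Ba and Cd74.

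Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 348 genes, and the highest other split gave 1 gene. Every other split mixed libraries of both groups, so any difference between the groups would itself widen the spread and lower the calls there. For lists, 2 of the 10 splits gave as many as the real 9, the other being non-loaded replicates 1 and 2 with spironolactone replicate 1 against the rest, with 10 lists. In both cases 10 splits are too few for a share under 0.05. For lists, moreover, a mixed split called more than the real one. That outcome had been written down beforehand for a grouping without meaning, so the number of lists called does not set the real groups apart.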
